A study of Homo sapiens with 6 samples.

How the data were processed

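RNA of PC9 lung adenocarcinoma cells was sequenced in 6 libraries, 3 treated with an antagomir against tsRNA-5001a and 3 with a negative control antagomir. Per the labels' protocols, sequencing was on an Illumina platform, reads passed quality control, were mapped to a reference genome and were counted per gene by the authors. The aligner, the counting program and whether counting used strand are not given in the sources used here. The deposited table holds whole-number counts, TPM and FPKM per gene and library for 58174 genes, and all results here come from the deposited counts. The TPM and FPKM values deposited by the authors were not used for any test. The submitters' processing notes name hg19. Of 57836 genes shared with GENCODE release 29 on GRCh38, 56001 (96.8%) had identical chromosome, start and end in the deposited table, so printed coordinates are those of the table and match GRCh38. Some small genes, such as SNORD118, stand at exactly 1 count in each library of a group, the reason for which is not given.

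Groups were taken from the labels. Genes were filtered with filterByExpr at a minimum of 10 counts, which left 19040, and scaled by TMM. Genes were tested with edgeR 4.0.16 in R 4.3.3 by a quasi-likelihood F-test, with Benjamini-Hochberg adjustment at 0.05. CPM are counts scaled by the TMM-scaled library total, in the usual unit, and errors are SD over 3 libraries unless named as standard errors. Standard errors of log2 fold changes were back-calculated from the fold change and the F statistic of the test. A fold against a group at 0 counts was taken against 3 counts over the group, which covers counting error only. The biological coefficient of variation was 22.9%. Chi-square per degree of freedom between libraries of 1 group was 33.4 to 83.2, so no libraries were counted as 1. Totals of 32342017 to 40066223 counts per library were checked in simulated data of 19040 genes, of which 18563 were tested. There 4.48% of genes changed 1.5-fold were recovered, 37.3% at 2-fold and 89.4% at 4-fold, with 8 unchanged genes called. The genes changed at these folds were drawn from those with a mean of at least 1 CPM outside the lists. In the simulation 2 of 2 shifted lists and 0 unshifted lists were called. The simulated genes were drawn independently of each other, so this cannot show how often lists of correlated genes are called falsely.

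The 30 gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with estimated correlation and fry as alternatives, and adjusted over the lists. The lists, the tests and the rule for named genes were fixed before the data were examined. The rule took the GADD45 genes and the 8 largest rises and falls past the test, of at least 1 log2 CPM, with non-overlapping libraries and a regular symbol. It added up to 4 members of each list that passed camera or had at least 3 members past the test, and up to 2 of other lists, which gave 98 genes. Genes named only in the closing observations were outside it and were chosen after their values were seen.

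The alternatives fixed before the data were examined were DESeq2 size factors, upper-quartile and library-size scaling, no filter or a stricter filter, DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library, a test against a fold of 1.2 and an adjusted p of 0.01. Chosen after seeing the data were removal of GC and length trends, removal of the abundance trend, restriction to protein-coding genes and other scalings of the list tests. Named genes were followed under 14 settings. The other filters, protein-coding genes only, the test against a fold of 1.2 and the adjusted p of 0.01 were not among these. Gene types, lengths and GC content came from GENCODE 29. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.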

Results

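Messenger RNA levels were compared between PC9 cells, an established human lung adenocarcinoma line, treated with an antagomir against tsRNA-5001a and PC9 cells treated with a negative control antagomir. A tsRNA is a small RNA cut from a transfer RNA, and an antagomir is a chemically modified antisense oligonucleotide used to block a small RNA. Each group had 3 libraries. Total gene counts were 37294575, 32342017 and 40066223 in knockdown libraries 1 to 3, and 38297638, 34623672 and 39615278 in control libraries 1 to 3. The tsRNA itself is not measured by these gene counts, so the knockdown was not checked here. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

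GADD45G, a stress-inducible gene of the growth arrest and DNA damage family, was 9.57-fold higher after knockdown, at 15.1 ± 4.84 CPM (SD, n = 3) against 1.59 ± 0.577 in the control. GADD45A rose 2.45-fold, from 42.3 ± 3.83 to 103 ± 15.5 CPM. ARC, an immediate early gene, rose 44.2-fold, and the stress-induced transcription factor gene ATF3 rose 6.25-fold. OAS2, an interferon-stimulated gene, rose 5.51-fold, and CHAC1, a gene of the ATF4 stress response, rose 6.21-fold. Among the genes that fell were UCHL1, a ubiquitin hydrolase, and TYMS, which encodes thymidylate synthase. UCHL1 was past the test under 11 of the 14 settings followed for named genes, and TYMS under only 5.

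The question of the comparison was which transcripts differ when tsRNA-5001a is blocked. Of 19040 genes tested with edgeR's quasi-likelihood test, 223 passed a Benjamini-Hochberg adjusted p of 0.05. Of these, 209 rose and 14 fell, and 193 changed at least 2-fold, with 187 higher and 6 lower. Those 6 included SNORD118, RNU2-2P and AC008982.1, which had at most 1 count in every knockdown library. The others were LINC00094 and, with uncertain counts, ST20-MTHFS and RN7SL2. At an unadjusted p under 0.05 there were 3138 genes, 1861 higher and 1277 lower. CPM did not overlap between the groups for 4619 genes, 24.3% of those tested, where chance gives 10% on average. Where genes vary together, the share can lie far from 10% by chance, and its spread was not tested. Of the 223 genes, 82 were not protein coding, or 36.8% against 25.5% of all tested genes. The genes that rose had a median abundance of 0.72 log2 CPM against 3.72 for all tested genes. The share that rose was 93.7%, and DESeq2 called 446 genes higher and 194 lower. With GC and length trends removed, 338 were higher and 127 lower. The count of 223 fell when any library was left out, to 102, 75 and 64 without knockdown libraries 1, 2 and 3, and to 114, 88 and 87 without control libraries 1, 2 and 3.

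GADD45G (ENSG00000130222) lies on chromosome 9 at 89605013 to 89606555 on the plus strand, in coordinates that match GRCh38. Its log2 fold change was 3.26 with a standard error of 0.35 and an edgeR adjusted p of 0.00526. Its CPM was 19.4, 9.89 and 16.1 in the knockdown libraries and 1.02, 2.17 and 1.57 in the controls. GADD45A (ENSG00000116717; chromosome 1, 67685061 to 67688338) had a log2 fold change of 1.29 with a standard error of 0.15 and an edgeR adjusted p of 0.00839. GADD45B, the remaining member of the family, was at 20.3 ± 2.85 against 13.8 ± 4.52 CPM, with a log2 fold change of 0.56 and an edgeR adjusted p of 0.288. The difference between the family members was not tested.

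**Figure D1:**
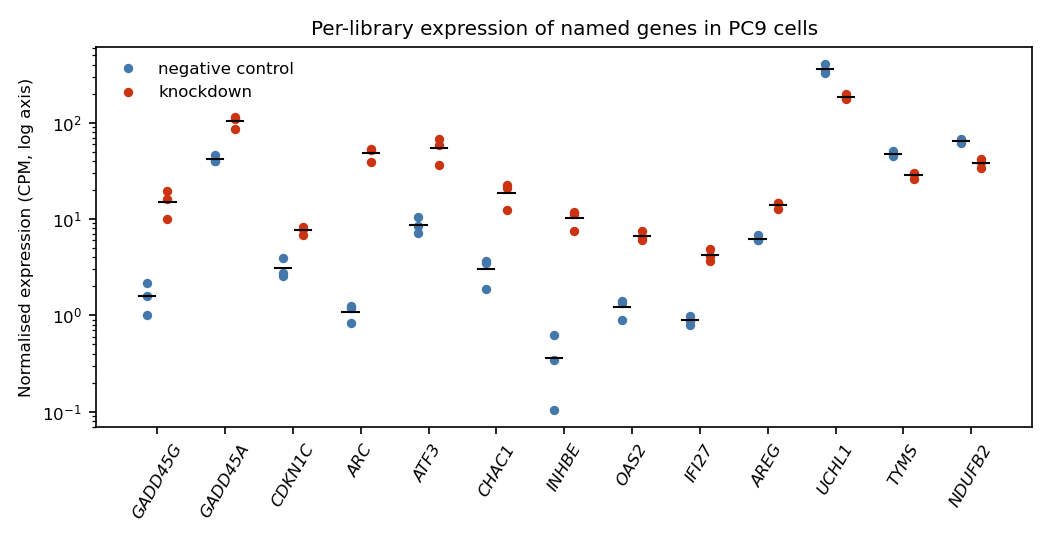
Normalised expression in CPM on a log axis for 13 genes in each of the 3 control and 3 knockdown PC9 libraries; points are libraries and bars are group means. GADD45G lies between 9.89 and 19.4 CPM in knockdown libraries and between 1.02 and 2.17 in control libraries, and UCHL1, TYMS and NDUFB2 lie lower in knockdown libraries.

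Among genes of at least 1 log2 CPM with a regular symbol whose libraries did not overlap, LINC01647 had the largest rise. It went from 0 counts in all control libraries to 4.24 ± 0.504 CPM. Against a floor of 3 counts over the control group this was at least 153-fold higher. AC012447.1, left out for its clone-type symbol, had a log2 fold change of 6.99. Its edgeR adjusted p of 2.4e-05 was the lowest of all genes. ARC (ENSG00000198576; chromosome 8, 142611044 to 142614472) rose from 1.09 ± 0.228 to 48.3 ± 8.07 CPM, a log2 fold change of 5.47 with an edgeR adjusted p of 5.2e-05. SYNE1, which encodes a nuclear envelope spectrin-repeat protein, rose with a log2 fold change of 5.20 (edgeR adjusted p 0.000441). INHBE, an inhibin beta subunit gene, rose by 4.85 on the log2 scale, and DLL4, a Notch ligand gene, by 4.14. RFPL4A and RFPL4AL1, with log2 fold changes of 5.45 and 5.49, are near-identical copies, and one of many U1 small nuclear RNA copies (ENSG00000270722) had 4.63. Values of these 3 genes are uncertain because the counting could have split reads between copies.

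Under the same limits on abundance, overlap and symbol, the largest fall was that of LINC00094. It fell by 1.57 on the log2 scale, from 31.7 ± 8.47 to 10.7 ± 1.10 CPM (edgeR adjusted p 0.0158). ST20-MTHFS fell by 1.54, but this read-through gene overlaps its parent genes, so its counts are uncertain. RN7SL2, a copy of the signal recognition particle RNA, fell by 1.22, with reads that may be shared between copies. UCHL1 (chromosome 4, 41256413 to 41268455) fell by 0.95, from 357 ± 41.1 to 185 ± 11.5 CPM, with an edgeR adjusted p of 0.0148. The amino acid transporter gene SLC7A6 fell by 0.98, TSTA3 by 0.96, the mRNA decapping enzyme gene DCP2 by 0.88 and NDUFB2, a subunit gene of respiratory complex I, by 0.77. These falls depended on the setting. Of 14 settings, LINC00094 and ST20-MTHFS were past the test in 10, RN7SL2 in 8 and NDUFB2 in 6. SLC7A6 and TSTA3 were past it in 5 and DCP2 in 3.

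Of the 30 gene lists fixed before the data were examined, 13 passed an adjusted p of 0.05 with camera at a preset correlation, 6 upward and 7 downward. With an estimated correlation 0 of the 13 passed, and the lowest adjusted p was 0.0622. fry, which asks whether a list moves one way on balance, called 14 lists, of which 11 were among these 13. It did not call G2/M and mitosis or the mitochondrially encoded genes (both adjusted p 0.194), and it called p53 targets (0.0219), EGFR and MAPK output (0.0281) and replication-dependent histones (0.0436), which camera did not. The test and the median differed in sign for 2 lists, hypoxia and glycolysis and small RNA and tRNA processing, and neither passed.

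Interferon-stimulated genes were higher as a list, with a median log2 fold change of 0.36 and 40 of 43 tested members above 0 (camera adjusted p 9.6e-10; adjusted p = 0.153 with an estimated correlation). In it 5 members rose over all genes and 15 adjusted over the list alone. OAS2, an antiviral oligoadenylate synthetase, rose from 1.21 ± 0.276 to 6.65 ± 0.743 CPM (log2 fold change 2.46, edgeR adjusted p 0.00411). IFI27 rose by 2.25 on the log2 scale, IFI44 by 1.65 and IFI6 by 1.57. For NF-kB and inflammatory cytokine genes, 3 of 30 rose over all genes and 8 adjusted over the list alone (camera adjusted p 0.00345; adjusted p = 0.324 with an estimated correlation). These were IL6, from 2.44 ± 0.195 to 5.57 ± 1.04 CPM, and the acute phase genes SAA1 and SAA2, whose similar sequences make their separate values uncertain. Without control library 1 the camera adjusted p of this list was 0.0569.

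Of 31 ATF4 integrated stress response genes, 5 rose over all genes and 12 adjusted over the list alone (median log2 fold change 0.33, camera adjusted p 1.3e-07; adjusted p = 0.0622 with an estimated correlation). The median was 0.22 without knockdown library 2. ATF3 rose from 8.62 ± 1.66 to 54.0 ± 16.2 CPM. CHAC1, a glutathione-degrading enzyme gene, rose from 3.01 ± 0.972 to 18.8 ± 5.53 CPM, a log2 fold change of 2.64 with an edgeR adjusted p of 0.00973. PPP1R15A, a phosphatase subunit gene of this response, rose by 0.83 on the log2 scale, and ASNS, asparagine synthetase, by 0.86. Of 29 immediate early genes 4 rose over all genes, and 10 rose and 1 fell adjusted over the list alone (camera adjusted p 1.5e-07; adjusted p = 0.168 with an estimated correlation). The list median was 0.14, from 0.03 without knockdown library 1 to 0.29 without control library 3. The 4 that rose over all genes were ARC, ATF3, KLF4 and NR4A3, with KLF4 at 67.8 ± 1.21 against 26.2 ± 9.94 CPM. NR4A3 was of low abundance, at 1.29 ± 0.198 against 0.0884 ± 0.0814 CPM.

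In the list of the GADD45 family and inhibitors of cyclin-dependent kinases, 3 of 12 members rose over all genes and 5 adjusted over the list alone (camera adjusted p 0.00139; adjusted p = 0.294 with an estimated correlation). The third was CDKN1C, which encodes the kinase inhibitor p57, from 3.08 ± 0.749 to 7.59 ± 0.739 CPM. CDKN1A had a log2 fold change of 0.44 and an edgeR adjusted p of 0.139. Of 24 YAP/TEAD targets, GADD45A and ANKRD1 rose over all genes and 4 adjusted over the list alone (camera adjusted p 0.000281; adjusted p = 0.212 with an estimated correlation). ANKRD1 rose by 1.26 on the log2 scale (edgeR adjusted p 0.0125). Some genes stand in more than 1 list.

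All 75 cytosolic ribosomal protein genes tested were lower after knockdown, with a median log2 fold change of -0.42 (camera adjusted p 1.4e-31; adjusted p = 0.288 with an estimated correlation). None passed over all genes, where 0 fell, and 66 fell adjusted over the list alone. RPL32 was at 546 ± 48.9 against 808 ± 61.6 CPM, with an edgeR adjusted p of 0.0628. The median was -0.20 with the abundance trend of each library removed. Of 47 nuclear-encoded respiratory chain genes, NDUFB2 fell over all genes and 38 fell adjusted over the list alone. Their median was -0.42 (camera adjusted p 9.7e-20, and adjusted p = 0.212 with an estimated correlation). Over 13 settings, removal of the abundance trend among them, their highest median was -0.298, with library size only. At the preset correlation this list passed camera in all 13. The 13 mitochondrially encoded genes had a median of -0.40 and 0 past the gene test on either adjustment (camera adjusted p 2.7e-05; adjusted p = 0.373 with an estimated correlation). With the abundance trend removed that median was -0.03 and the adjusted p 0.525, and without control library 2 the median was -0.18. Beside these lists, the 577 genes above 8 log2 CPM had a median log2 fold change of -0.17, and genes under 1 log2 CPM a median of 0.29.

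**Figure D2:**
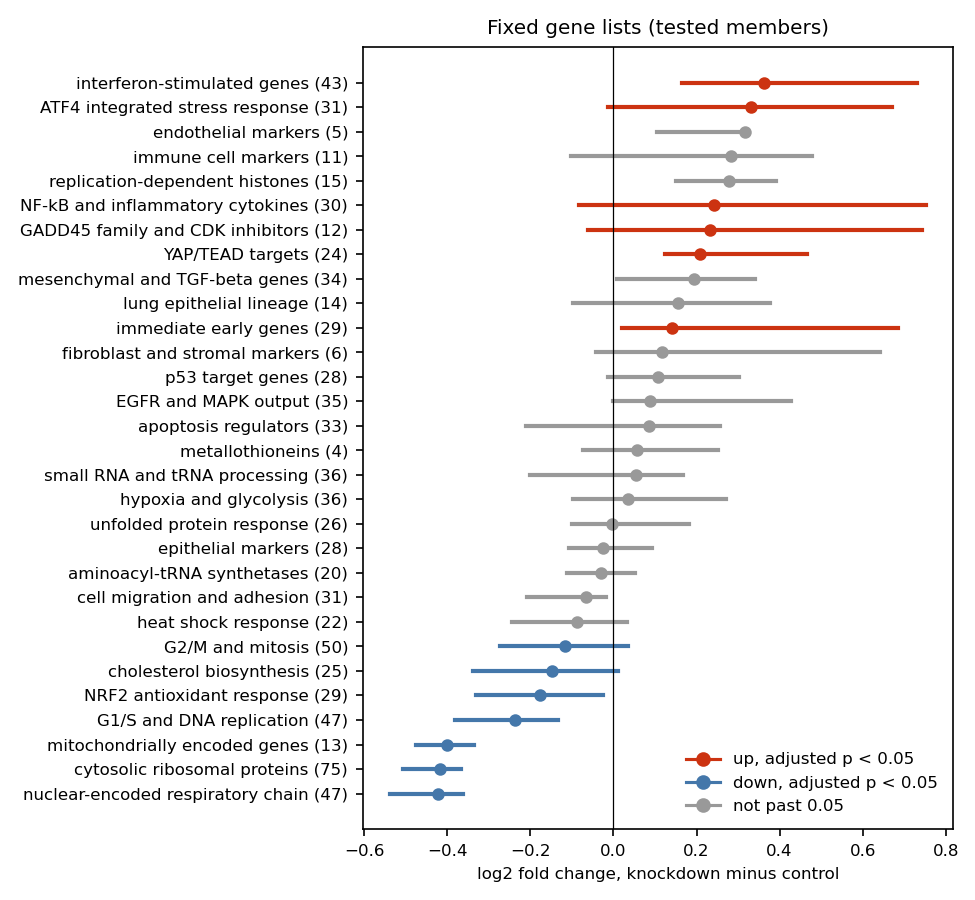
Median log2 fold change, knockdown minus control, of the tested members of 30 fixed gene lists, with lines from the lower to the upper quartile and the number of members in brackets; colour marks lists past a camera adjusted p of 0.05 at a preset correlation. Interferon-stimulated genes have a median of 0.36 and ribosomal protein genes a median of -0.42, and 0 lists passed with an estimated correlation.

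Of 47 genes of the G1/S transition and DNA replication, 43 were lower, TYMS fell over all genes and 11 fell adjusted over the list alone (median -0.24, camera adjusted p 5.5e-09; adjusted p = 0.0622 with an estimated correlation). TYMS fell by 0.74 on the log2 scale, from 47.5 ± 2.48 to 28.4 ± 1.87 CPM, with an edgeR adjusted p of 0.0367. The replicative helicase gene MCM7 had a log2 fold change of -0.51 and an edgeR adjusted p of 0.0912. Of 50 genes of G2/M and mitosis 0 passed on either adjustment (median -0.12, camera adjusted p 0.000636; adjusted p = 0.367 with an estimated correlation). Their camera adjusted p was 0.0751 without knockdown library 1, and their median was -0.24 without knockdown library 2. Of 29 NRF2 targets 0 passed over all genes and 1 fell adjusted over the list alone (median -0.18, camera adjusted p 0.000149; adjusted p = 0.212 with an estimated correlation). Of 25 cholesterol biosynthesis genes 0 passed on either adjustment (median -0.15, camera adjusted p 0.00345; adjusted p = 0.212 with an estimated correlation). With the abundance trend removed the medians of these NRF2 and cholesterol lists were -0.03 and -0.06, with adjusted p of 0.705 and 0.0587. The NRF2 median was -0.27 without control library 1, and the cholesterol median was -0.32 without knockdown library 1. Scaled by library size only, where the median of all genes was 0.17 against 0.05, the medians were -0.12 for G1/S, 0.01 for G2/M, -0.05 for NRF2 and -0.03 for cholesterol genes.

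The other 17 lists did not pass the camera test. Some passed under alternatives at the preset correlation. Of 13 settings, fibroblast and stromal markers passed in 7 and cell migration and adhesion in 5. EGFR and MAPK output and p53 targets passed in 4 each, and the heat shock response in 2. Mesenchymal and TGF-beta genes and epithelial markers passed in 1 each. Of 28 p53 targets GADD45A rose over all genes and 3 rose adjusted over the list alone (camera adjusted p 0.103). Of 35 genes of EGFR and MAPK output, the EGFR ligand genes AREG and HBEGF rose over all genes and 5 adjusted over the list alone (camera adjusted p 0.071). AREG rose from 6.27 ± 0.452 to 14.0 ± 1.23 CPM, and HBEGF rose by 1.19 on the log2 scale. Of 34 mesenchymal and TGF-beta genes SPARC rose (camera adjusted p 0.193). Of 6 fibroblast and stromal markers PDGFRB rose from 0.835 ± 0.183 to 6.38 ± 1.81 CPM (camera adjusted p 0.0552). No member passed over all genes among immune cell markers (camera adjusted p 0.471) or endothelial markers (0.712). The same held for lung epithelial lineage genes (0.651), epithelial markers (0.651), cell migration and adhesion (0.0509) and apoptosis regulators (0.906). It also held for the heat shock response (0.103), the unfolded protein response (0.716), metallothioneins (0.716) and replication-dependent histones (0.122). It held as well for aminoacyl-tRNA synthetases (0.611), small RNA and tRNA processing (0.509) and hypoxia and glycolysis (0.665).

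**Figure D3:**
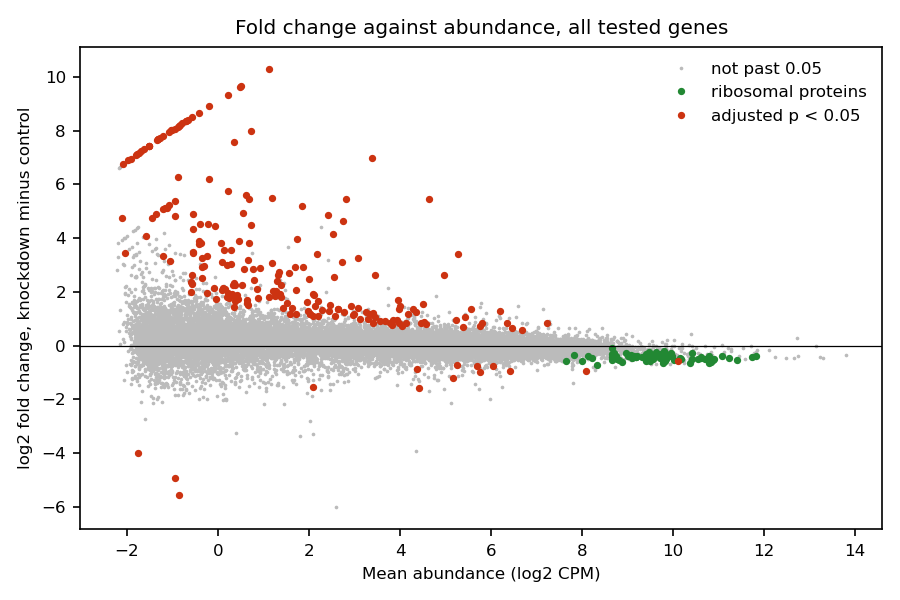
Log2 fold change, knockdown minus control, against mean abundance in log2 CPM for all 19040 tested genes; red points are the 223 genes past an edgeR adjusted p of 0.05 and green points are ribosomal protein genes. Most red points are rises at low abundance, and the fitted values of genes with 0 control counts form the straight upper line.

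At equal depth, genes with at least 10 counts numbered 18849, 19041 and 19221 in the knockdown libraries and 18059, 17944 and 17877 in the control libraries. The top 10 genes took 6.79% to 7.79% of counts in the knockdown libraries and 7.51% to 9.02% in the controls. MALAT1 was at 272 CPM in knockdown library 2 and between 63.7 and 106 CPM in the other libraries. The first principal component held 41.0% of the variance and separated the groups. Of 38 named genes past the test, 12 stayed past it under all 14 settings tried. The 12 were ARC, ATF3, CHAC1, DLL4, INHBE, LINC01647, OAS2, PDGFRB, RFPL4A, RFPL4AL1, SYNE1 and the U1 copy. GADD45G, GADD45A and IFI27 were past it under 13 settings, KLF4 and TYMS under 5, IL6 under 4 and DCP2 under 3. The call was lost for 16, 18 and 23 named genes without knockdown libraries 1, 2 and 3, and for 19, 17 and 21 without control libraries 1, 2 and 3.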

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

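Chosen after the data were seen were removal of GC and length trends, removal of the abundance trend and restriction to protein-coding genes. So were the other scalings of the list tests. The cause of each shift was not tested. Against 223 genes past an adjusted p of 0.05 and 193 at 2-fold, the counts were 191 and 170 with DESeq2 size factors, 229 and 199 with upper-quartile scaling, 319 and 265 with library size only, and 220 and 192 with limma-voom. DESeq2 gave 640 and 400, of which 222 and 191 were shared. No filter gave 147 and 140, a stricter filter 67 and 59, GC and length removal 465 and 249, abundance trend removal 126 and 114, and protein-coding genes only 97 and 82. An adjusted p of 0.01 left 45 genes and a test against a fold of 1.2 left 156. Leaving out 1 library gave 64 to 114 genes and 64 to 113 at 2-fold. The replicate number as a block gave 34 and 34 genes, all higher; same-numbered libraries deviated with correlations of 0.01, -0.08 and -0.03, so the numbers do not pair the libraries. Of 30 lists, 0 passed with an estimated correlation and 13 to 16 under the other settings; of the 13 that passed first, 10 did so with the abundance trend removed, 11 with fry, 12 without knockdown library 1 or control library 1, and 13 under the rest. The epithelial marker median turned from -0.03 to 0.142 (adjusted p 0.0377) with the abundance trend removed, where adjusted p over its 13 settings ran from 0.0377 to 0.972. With 3 libraries per group and the spread of these data, 4.48% of simulated 1.5-fold changes were recovered. Changes of that size were thus mostly not detectable, and other depths were not simulated.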

Other observations

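The tests of U1 and U3 copies, other non-polyadenylated RNAs and zinc finger genes, and 2 of the 3 genomic DNA tests, were chosen only after the result was seen, and removal of GC and length trends or of the abundance trend only after the data were seen. Other genes that rose, named after their values were seen, included PGF, a placental growth factor gene, from 8.52 ± 1.14 to 23.5 ± 2.84 CPM, and NRG1, an ERBB ligand gene, from 1.02 ± 0.215 to 3.77 ± 0.410 CPM. HIST2H4A, a histone gene, had a log2 fold change of 1.93 (edgeR adjusted p 0.0069) that is uncertain because it has a near-identical copy.

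Zinc finger genes of chromosome 19 were noticed among the genes that rose and then counted there, so the count describes these genes and is not independent evidence. Of 185 tested, 7 rose and 0 fell, against 123 of 14007 that rose among other protein-coding genes, an odds ratio of 4.44 (95% interval 1.72 to 9.61; Fisher's exact test, two-sided p 0.00157, which takes genes as independent). Those 7 were ZNF571, ZNF471, ZIK1, ZNF583, ZNF227, ZNF582 and ZNF222. Over all 185, camera gave p = 1.4e-05 at the preset correlation and p = 0.105 with an estimated correlation, so a shift of the group stays open. With GC and length trends removed, 8 of these genes rose, an odds ratio of 2.94 (Fisher's exact test, two-sided p 0.00826). Over all 185, camera with an estimated correlation then gave p = 0.0222. An excess thus remained after that removal, with a lower odds ratio. The group was picked from the rises in these data, and the Fisher test takes genes as independent. How far GC and length trends account for the excess therefore stays open. The genes are the same, so these values are not independent evidence of a shift. The median of 0.29 lay above the highest of 10000 abundance-matched random lists, 0.198, but such lists also take genes as independent, so low abundance stays open.

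All 75 ribosomal protein genes were lower, by a median of -0.42. With GC and length trends removed the median was -0.39, and with any 1 library left out the highest was -0.34, without control library 2, so neither that bias nor 1 library accounts for it. Removal of the abundance trend left -0.20, at the edge of a bound set before that value was seen, so a trend over all abundant genes could account for part of it and cannot be told apart from a lower level of these mRNAs. These genes are themselves among the most abundant and help to set that trend.

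In all, 37 genes had 0 counts in every control library and at least 10 in every knockdown library, 33 of them past the test and 19 protein coding, among them POU3F1, FRG2 and SCRT1. The reverse held for 0 genes, or for 3 against 43 if up to 1 count per library is allowed, as for SNORD118 and RNU2-2P, whose single counts are unexplained, which argues against noise of low counts. HBA1 had 370 counts and HBB 0 over the knockdown libraries, which argues against erythroid cells as the source of HBA1 and HBA2. Genomic DNA was tested 3 times and stays open as a source of part of these counts. The test set beforehand, on 442 receptor and beta-defensin genes, gave a ratio of 1.02 and met its bound. However, 11 expressed genes held 90.2% of that control sum and would hide a small share. The 431 genes below the filter gave 1.64 (3.24 ± 0.296 against 1.98 ± 0.156 CPM), between its bounds. The last test gave 0.288 counts per such gene and knockdown library, against a median of 28.7 for the genes absent in control. Median transcript lengths were 1079 and 1581. Only 11 of the 442 genes passed the filter and were left out here, so the low value holds for nearly all of them. Both sets were picked by their counts, low for these genes and high for the genes absent in control. The size of the gap is therefore partly set by that choice. Low counts of nearly all 442 genes argue only against genomic DNA spread evenly over genes as the whole source. Unevenly spread genomic DNA stays open.

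U1 and U3 small RNA genes were higher: summed over 145 U1 copies, 42.6 CPM (libraries 38.0 to 45.0) against 15.5 CPM (8.23 to 21.9), and over 6 U3 copies, 20.6 ± 2.77 against 2.42 ± 0.893 CPM. A set of 7 more non-polyadenylated RNAs had a median log2 fold change of -0.82, or -0.18 without the 2 that stood at exactly 1 count in every knockdown library. They leave out RNU4ATAC and 4 histone genes, also not polyadenylated, that rose (log2 fold change 4.51 for RNU4ATAC and 1.93 for HIST2H4A). RNU4ATAC lies inside AC012447.1 on the same strand, a longer gene with a log2 fold change of 6.99. Its counts may therefore be reads of that gene. The fixed list of 15 replication-dependent histones had 0 past the test and a camera adjusted p of 0.122. Its median was 0.28 (0.14 without knockdown library 2). Carry-over of such RNA therefore stays open. For reads moved between copies, 2 bounds were tried: the first, the lowest knockdown over the highest control library, asked for 2 and gave 6.06 for U3 and 1.73 for U1, which left U1 undecided; the second, set after these values were seen, took ratios of means, 2.75 for U1 and 8.52 for U3, with no overlap. For U3 both bounds argue against it, and for U1 only the bound set after the fact does.

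There are 10 splits of the 6 libraries into 3 and 3, so the share of splits with a result as large cannot be under 0.1, and 1 split, the real one, gave each result. The real values were 223 genes, 193 at 2-fold and 13 lists, and the highest of the other splits were 5, 5 and 9. Every other split has libraries of both groups in each arm. A group difference then adds to the spread within arms and lowers the gene counts. The other splits therefore do not show what libraries without a group difference would give.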
